A study of Mus musculus with 12 samples.

How the data were processed

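RNA of sorted mouse tumour cells was measured by low-input bulk RNA-seq in 12 libraries, 4 from each of 3 populations. Per the labels' protocols, cells were lysed in TCL buffer, RNA was purified on beads, reverse transcribed, amplified by PCR and tagmented into libraries. The protocol names no strand marking and no molecular identifiers, so amplified copies cannot be told from separate molecules and overlapping antisense genes cannot be told apart. The authors deposited a table of estimated counts per gene and a table of TPM (transcript abundance scaled for length and total), each with 55291 gene symbols and a column per library. Between 7.53% and 9.49% of the deposited estimated counts in a library were not whole numbers. STAR 2.6.1d, Salmon 0.13.1 and DESeq2 1.34.0 and the genome builds GRCm38 and mm10 are named in the submitters' processing notes, without their roles. The annotation the authors used and their filters are not given in the sources used here. Of the symbols, 53292 matched GENCODE M21 on GRCm38, which gave the positions, transcript lengths and GC contents used here.

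Each column was assigned to a library by the population and replicate number in its name, and each library to a population by its title. Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr by population, with a minimum count of 10 and a minimum total of 15, which left 13394 genes. Library sizes were scaled with TMM factors, and CPM were computed on the scaled sizes. The quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation) was fitted with a term for each population over all 12 libraries, leaving 9 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Adjusted p-values given beside a gene come from this test, and it is two-sided. R 4.3.3 was used, with Python 3.11.15 and matplotlib 3.10.9 for tables and figures.

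A set of 24 gene lists was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation. Camera p-values were adjusted over the 24 lists of each comparison, and lists with under 3 measured members were left out. The lists were MHC class II presentation, angiogenic and growth factors, hypoxia response, glycolysis, oxidative phosphorylation, interferon-stimulated genes, lipid-associated macrophage genes, alternative activation, chemokines, inflammatory cytokines and NF-kB targets, T cell suppression, proliferation, and immediate-early and dissociation genes. Marker lists covered monocytes, neutrophils, macrophages, dendritic cells, T and NK cells, B cells, eosinophils with mast cells and basophils, epithelium, fibroblasts, endothelium and red cells. A separate list of gate markers was described and not tested. Of the genes listed, 1, a neutrophil gene, had no match in the tables. Of each list, members past the gene test were counted over all genes tested and again with p-values adjusted over the list alone.

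The populations, the tests, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Genes were named by rule. The gate markers were named in every population. For Angio against MHCII the 8 genes with the largest rise and the 8 with the largest fall were named, and for the other comparisons 6 and 6. These had an adjusted p under 0.05, a mean of at least 8 CPM over both groups, no overlap between the libraries of the groups, and a symbol that is no predicted gene, pseudogene or receptor segment. From each list up to 3 members with the largest absolute log2 fold change were eligible, under the same limits on p and CPM. Where none passed, the member with the highest CPM was taken. The text names part of these genes, and 1 of those the rule takes is not reported here and was left out of the comparison of libraries within populations.

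The test was checked on simulated counts drawn from the means and library sizes of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. Of genes changed 2-fold it recovered 13% for Angio against MHCII, 15% for Angio against Mono and 14% for MHCII against Mono, and of those changed 4-fold 71%, 71% and 74%. False calls numbered 3, 1 and 6. Of 10 shifted lists 10 were called in each comparison and of 10 unshifted lists 0. Every member of a shifted list was changed and genes were drawn independently, so the list check does not test the preset correlation. In the real comparisons 40.5% to 54.4% of genes were called. With so few genes changed, the adjusted threshold was stricter in the simulation, and its recovery may understate that of the real test. A gene that was not called may still differ by 2-fold at this depth and spread.

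The alternatives were DESeq2 median-ratio and upper-quartile factors in edgeR, no low-count filter, at least 10 counts in 8 libraries, the Wald test of DESeq2 1.42.0, a fit of the 2 groups compared alone, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), log2(TPM + 1) without the filter, and each library left out in turn. After the data were seen 3 more were added, namely leaving out the libraries Mono 1, Angio 2 and MHCII 2, leaving out CT010467.1 (annotated as ribosomal RNA), mitochondrial and haemoglobin genes, and offsets for GC content and transcript length. Values on the TPM scale depend on the pseudocount, which understates the changes of low genes. The median log2 fold change of all genes, Angio against Mono, shifted by 0.107 with upper-quartile factors, 0.125 with log2(TPM + 1) and 0.167 with log2(TPM + 0.1), and that of MHCII against Mono by 0.14 with GC and length offsets. Without MHCII 2 the median of Angio against MHCII shifted by 0.106. It shifted by 0.116 with unfiltered TPM, and by 1.09 without a filter and 1.25 with DESeq2, both on 37801 genes. In these 2 settings Angio against Mono shifted by 0.542 and 0.741 and MHCII against Mono by -0.161 and -0.2. Genes highest in a population passed both tests that involve it. The overlap of both Ly6C/G-negative populations against Mono was set beside 20 simulations of unchanged groups against the same Mono libraries. No library and no deposited column was left out of the main test.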

Results

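Bulk RNA-seq was measured in 12 libraries of myeloid cells sorted from subcutaneous 4T1 tumours, 4T1 being a transplantable mouse mammary carcinoma line. Each of 3 sorted populations had 4 libraries. The Mono population held CD45+ CD11b+ cells positive for Ly6C/G, a stain for monocytes and neutrophils. The other populations were Ly6C/G-negative tumour-associated macrophages by their labels. Those called pro-angiogenic were sorted as negative for CX3CR1 and MHC class II, and are written Angio here. Those positive for both markers are written MHCII. Estimated counts summed to between 9750312 and 10130092 per Mono library, 6114385 and 10265370 per Angio library, and 11181514 and 13896256 per MHCII library. The number of genes with a count ran from 22054 to 22813 in Mono, 24635 to 28827 in Angio and 19269 to 20805 in MHCII. Gene levels below are mean CPM (counts scaled to library size) ± SD over the 4 libraries of a population (n = 4), and log2 fold changes carry their standard error (SE). The labels do not say whether libraries of a population came from separate animals, so p-values measure the spread between these samples, which may be technical.

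Transcripts of the sorted markers separated the populations only in part, which describes the sort and is no finding. H2-Ab1, a chain of the MHC class II molecule, stood at 3368 ± 239 CPM in MHCII, 732 ± 39.8 CPM in Mono and 83.2 ± 6.26 CPM in Angio. Cx3cr1, the fractalkine receptor gene, stood at 1.83 ± 1.32 CPM in Angio and 50.8 ± 23.0 CPM in MHCII. In Mono it stood at 42.1 ± 7.40 CPM, a level that did not pass the test against MHCII (edgeR adjusted p = 0.617). Without Angio 2 the Angio mean of Cx3cr1 was 1.19 CPM. Ly6c2 was highest in Mono, at 155 ± 25.2 CPM, against 26.4 ± 5.89 CPM in Angio and 39.3 ± 6.99 CPM in MHCII. Ly6g, a neutrophil surface protein, stood at 83.8 ± 12.2 CPM in Mono, 32.5 ± 9.17 CPM in Angio and 0.373 ± 0.304 CPM in MHCII. Angio thus held Ly6g transcript well above MHCII, although both were sorted as Ly6C/G-negative. Ptprc and Itgam, which encode CD45 and CD11b, were detected in all 3 populations. Component 1 of a principal component analysis of the 500 most variable genes held 61.94% of their variance and component 2 held 27.57%, and the 12 libraries formed 3 groups that matched the sort. CT010467.1, which the GENCODE M21 annotation of GRCm38 types as ribosomal RNA (chromosome 17 from 39846353 to 39848827, minus strand), took 7.37% ± 2.37 of the counts in Angio, 1.77% ± 0.273 in Mono and 0.888% ± 0.513 in MHCII. Its share can follow RNA quality or the removal of ribosomal RNA as well as expression, which the counts cannot separate. Without it and the mitochondrial and haemoglobin genes, a setting chosen after the data were seen, 1 call of a named gene ended, that of Uqcrc2 in Angio against Mono. Haemoglobin genes took 0.563% ± 0.237, 0.104% ± 0.018 and 0.167% ± 0.0916 of the counts in the same order. The library MHCII 2 had the lowest TMM factor of all, 0.6845, against 0.819 to 1.245 in the other libraries. Within their populations Mono 1, Angio 2 and MHCII 2 lay apart from the other 3 libraries in 14, 14 and 15 of the values examined. Angio 2 had 3040 CPM of Retnla and 52.4 CPM of Gzma, against 7030 to 7290 and 95.9 to 102 CPM in the other Angio libraries. Counts without these 3 libraries, and with GC and length offsets, were chosen after the data were seen, and are given below for each list with a count that moved by over 1.5 times or from or to 0.

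**Figure D1:**
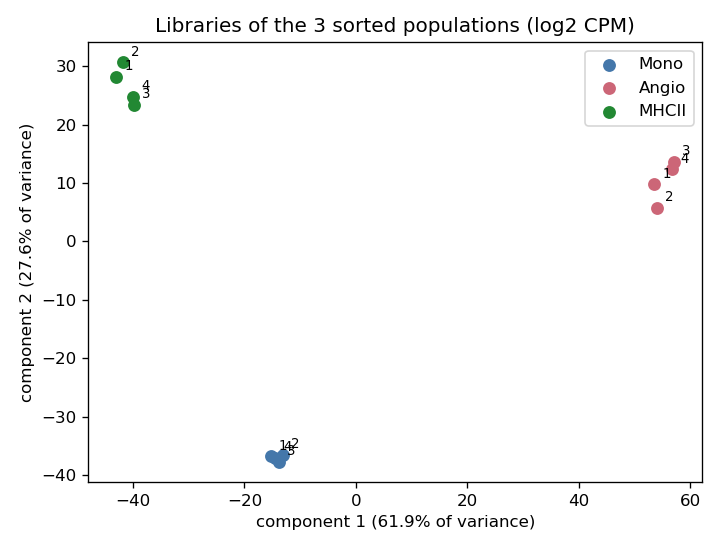
Principal components 1 (x axis, 61.94% of variance) and 2 (y axis, 27.57%) of log2 CPM for the 500 most variable genes, in arbitrary units. Each point is a library, coloured by population and numbered by replicate, and the 4 libraries of each population lie together.

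The comparison of Angio with MHCII asked how the cells labelled pro-angiogenic macrophages differ from those labelled MHC-II-positive macrophages in the same tumour model. Granulocyte genes were among those with the largest rises in Angio, and MHC class II, dendritic cell and chemokine genes among those with the largest falls. Prg2, the major basic protein of eosinophil granules, stood at 643 ± 189.6 CPM in Angio and 4.89 ± 3.38 CPM in MHCII (log2 fold change 7.06, SE 0.48, edgeR adjusted p = 6.59e-08), with all 4 Angio libraries above all 4 MHCII libraries. Its MHCII mean was 3.21 CPM without MHCII 2. C1qb, a complement component made by tissue macrophages, stood at 29.8 ± 3.36 CPM in Angio and 1190.3 ± 212 CPM in MHCII (log2 fold change -5.32, SE 0.23, edgeR adjusted p = 1.64e-09), again without overlap of the libraries. Of 13394 genes tested, 3578 were higher and 3710 lower in Angio, together 54.4%, and 2926 and 2948 of them differed by at least 2-fold.

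Among the lists of cell type markers fixed in advance, 8 of 10 measured eosinophil, mast cell and basophil genes were higher in Angio than in MHCII and 0 were lower (median log2 fold change 5.11; camera adjusted p = 9.75e-06, and adjusted p = 0.0265 with an estimated correlation). Ccr3, the eotaxin receptor, stood at 1360.4 ± 250.5 against 23.2 ± 1.49 CPM, and Il5ra, the interleukin 5 receptor of eosinophils and basophils, at 93.4 ± 44.9 against 2.15 ± 1.0 CPM. Epx, eosinophil peroxidase, had 281 counts in Angio and 3 in MHCII, a ratio of 134 per unit of library size (95% exact binomial interval 45.3 to 653). It was named outside the rule, which asks for a mean of at least 8 CPM over both groups. Of 20 measured neutrophil markers 19 were higher and 0 lower (median 5.0; camera adjusted p = 1.31e-11, and adjusted p = 0.0265 with an estimated correlation). Retnlg stood at 7165 ± 2479.9 against 59.5 ± 41.5 CPM (39.0 CPM without MHCII 2), and the granule genes Camp and Ngp at 754 ± 262 against 4.65 ± 2.62 CPM and 450.4 ± 78.9 against 4.09 ± 1.70 CPM. Of 14 T and NK cell markers 11 were higher and 0 lower (median 1.62; camera adjusted p = 7.74e-04, but adjusted p = 0.0547 with an estimated correlation). Gzma, a cytotoxic granule protease, stood at 87.0 ± 23.2 against 5.60 ± 2.23 CPM, and Il2rb, an interleukin 2 receptor chain, at 84.4 ± 18.9 against 16.2 ± 3.52 CPM. All 5 red cell genes were higher (camera adjusted p = 0.0416, but adjusted p = 0.266 with an estimated correlation), Hba-a1 at 663 ± 267 against 159.7 ± 99.9 CPM. The red cell call ended without Angio 1, Angio 3, MHCII 1, MHCII 3 or MHCII 4 (camera adjusted p = 0.054 to 0.0938). Other genes with the largest rises included Cyp26a1, a retinoic acid-degrading enzyme, at 62.5 ± 17.4 against 0.331 ± 0.213 CPM, and Serpina11 at 27.1 ± 4.59 against 0.134 ± 0.119 CPM (0.0867 CPM without MHCII 4). Mgll, a monoacylglycerol lipase, stood at 96.1 ± 24.5 against 0.817 ± 0.294 CPM and Tesc at 63.0 ± 11.5 against 0.566 ± 0.183 CPM.

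All 12 MHC class II presentation genes were lower in Angio than in MHCII (median -4.91; camera adjusted p = 6.82e-11, and adjusted p = 0.0278 with an estimated correlation), as the gate on the protein selects, with H2-DMb1 at 10.03 ± 1.71 against 490.3 ± 125 CPM. Of 17 macrophage markers 14 were lower and 1 higher (median -3.87; camera adjusted p = 2.65e-07, and adjusted p = 0.00581 with an estimated correlation). The mannose receptor gene Mrc1 stood at 11.1 ± 2.29 against 361 ± 64.9 CPM, while the member that was higher, Adgre1, which encodes F4/80, stood at 651 ± 228 against 113 ± 57.5 CPM and was singled out after its values were seen. Of 15 alternative activation genes 13 were lower and 1 higher (camera adjusted p = 1.57e-07, and adjusted p = 0.0146 with an estimated correlation). Ccl17 and Ccl22, chemokines of CCR4, stood at 1.74 ± 0.672 against 110.0 ± 88.8 CPM and 0.429 ± 0.291 against 26.7 ± 4.11 CPM, and the member that was higher, the resistin-like gene Retnla, at 6097 ± 2038 against 98.7 ± 68.8 CPM. Without MHCII 2 the MHCII means were 66.4 CPM for Ccl17, 64.7 CPM for Retnla and 15.4 CPM for the lectin gene Cd209d. Of 12 dendritic cell markers 9 were lower and 2 higher (camera adjusted p = 0.00592, and adjusted p = 0.0347 with an estimated correlation), Cd209a at 6.95 ± 0.643 against 338 ± 178 CPM. Il12b, a subunit of interleukins 12 and 23, stood at 0.196 ± 0.135 against 22.9 ± 12.4 CPM, Cd209d at 0.0929 ± 0.108 against 24.8 ± 19.2 CPM (0.0554 CPM in Angio without Angio 1), and Cd209e at 0.518 ± 0.329 against 37.7 ± 5.63 CPM. Gpr171 stood at 11.4 ± 5.21 against 878 ± 147 CPM, H2-Ea at 51.6 ± 5.16 against 3679 ± 1704 CPM and the collagen gene Col14a1 at 0.487 ± 0.190 against 31.7 ± 2.95 CPM.

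Of the 22 angiogenic and growth factors 14 were lower in Angio than in MHCII and 4 higher (median -1.74; camera adjusted p = 0.00511, and adjusted p = 0.0471 with an estimated correlation). Osteopontin (Spp1) stood at 545 ± 126 CPM in Angio and 18375 ± 10475 CPM in MHCII, the metalloproteinase gene Mmp12 at 20.9 ± 6.12 against 934 ± 219 CPM, and placental growth factor (Pgf) at 3.08 ± 0.708 against 73.2 ± 22.6 CPM. The 4 members that were higher, named after their values were seen, were Vegfa (256 ± 231 against 59.3 ± 57.6 CPM; log2 fold change 2.11, SE 0.79, edgeR adjusted p = 0.0364), Mmp9 (429 ± 90.1 against 66.3 ± 11.9 CPM), Thbs1 (82.1 ± 17.0 against 19.5 ± 9.16 CPM) and Cxcl2 (1316 ± 175 against 738 ± 259.6 CPM). Without Angio 2 the Angio mean of Vegfa was 142 CPM (log2 fold change 1.33, edgeR adjusted p = 0.138), and its call also ended without MHCII 1 or MHCII 2 (edgeR adjusted p = 0.053 and 0.0964). The call of Cxcl2 ended without MHCII 1, MHCII 3 or MHCII 4 (edgeR adjusted p = 0.0529, 0.0515 and 0.0696). Vegfa and Mmp9 are known to promote vessel growth and Thbs1 to restrain it. Of 19 proliferation genes 17 were lower and 0 higher (camera adjusted p = 1.89e-07, and adjusted p = 0.0146 with an estimated correlation), the mitotic kinase gene Bub1 at 2.82 ± 0.851 against 37.9 ± 13.5 CPM. Of 23 interferon-stimulated genes 16 were lower and 1 higher (camera adjusted p = 1.52e-05, and adjusted p = 0.0185 with an estimated correlation), Ifi44 at 66.5 ± 17.2 against 1078 ± 723 CPM and the chemokine gene Cxcl9 at 0.339 ± 0.240 against 21 ± 12.7 CPM. Immediate-early genes, which tissue dissociation can induce, were higher in 9 of 13 members and lower in 1 (camera adjusted p = 0.0145, but adjusted p = 0.266 with an estimated correlation), the phosphatase gene Dusp1 at 12158 ± 474 against 1814 ± 252 CPM.

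Further lists passed with the preset correlation and not with an estimated one. Oxidative phosphorylation had 9 of 22 members lower and 0 higher (camera adjusted p = 0.0316, and 0.440 as the p with an estimated correlation). Without the 3 libraries that stood apart within their groups 6 members of this list were higher and 6 lower. Monocyte markers had 7 of 12 lower and 2 higher (adjusted p = 0.0412, and 0.0870 as the p with an estimated correlation), and lipid-associated macrophage genes 7 of 12 lower and 0 higher (adjusted p = 0.0173, and 0.0597 likewise). Chemokines had 8 of 13 lower and 1 higher (adjusted p = 0.00358, and 0.373 as the p with an estimated correlation). Ccl12, at 33.2 ± 12.1 against 1720.1 ± 1840.4 CPM, had 4450 CPM in MHCII 2 and 556 to 1160 CPM in the other MHCII libraries, whose mean was 809 CPM. T cell suppression genes had 7 of 10 lower and 2 higher (adjusted p = 0.0362, and 0.0860 as the p with an estimated correlation), Arg1 at 70.9 ± 15.7 against 788 ± 102 CPM. B cell markers had 4 of 6 lower and 0 higher (adjusted p = 0.0360, and 0.13 as the p with an estimated correlation). The oxidative phosphorylation call ended without Angio 2 or MHCII 2 (camera adjusted p = 0.0777 and 0.0976), as did that of monocyte markers (0.0502 and 0.0667). The B cell call ended without MHCII 1, MHCII 2 or MHCII 4 (0.073, 0.0662 and 0.0916). These lists did not pass camera: hypoxia response (2 of 18 higher, 8 lower, adjusted p = 0.159), glycolysis (2 of 16 higher, 5 lower, 0.380), epithelial markers (2 of 11 higher, 2 lower, 0.494), fibroblast markers (0 of 11 higher, 4 lower, 0.109) and endothelial markers (1 of 3 higher, 2 lower, 0.308). Inflammatory cytokines and NF-kB targets had 6 of 16 higher and 6 lower (adjusted p = 0.963), with a median log2 fold change of 0.04 and a mean of -0.19, opposite in sign. The median was 0.23 with the member of 3 or fewer counts in a population at its bound. Tnfaip3 and Il1a, both NF-kB targets, were higher, at 859 ± 201 against 128 ± 35.5 CPM and 388 ± 97.7 against 70.8 ± 30.7 CPM. Adjusted over the list alone, the counts were 8 lower for oxidative phosphorylation, 17 lower for interferon-stimulated genes, 2 higher for macrophage markers and 12 higher for T and NK cell markers, and equal to those above for the remaining lists.

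Without the low-count filter 7425 genes were higher in Angio than in MHCII, and DESeq2's Wald test called 6606, in place of 3578. The differences of Ly6c1 and Ly6c2 between Angio and MHCII lost significance with upper-quartile factors, and of the 18 lists called, 9 held with an estimated correlation. Without Mono 1, Angio 2 and MHCII 2, glycolysis genes had 9 of 16 lower in Angio than in MHCII and 3 higher, and epithelial markers 4 of 11 lower and 2 higher. Members higher were then 6 for oxidative phosphorylation, 3 each for lipid-associated macrophage genes and chemokines, 2 each for interferon-stimulated genes and macrophage markers, and 1 of 8 for B cell markers, and immediate-early genes had 2 lower. With GC and length offsets epithelial markers had 0 higher and 4 lower and immediate-early genes 3 lower. Members higher were then 2 each for macrophage markers, alternative activation and chemokines, 1 each for oxidative phosphorylation, lipid-associated macrophage genes, dendritic cell and fibroblast markers, and 0 for endothelial markers.

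**Figure D2:**
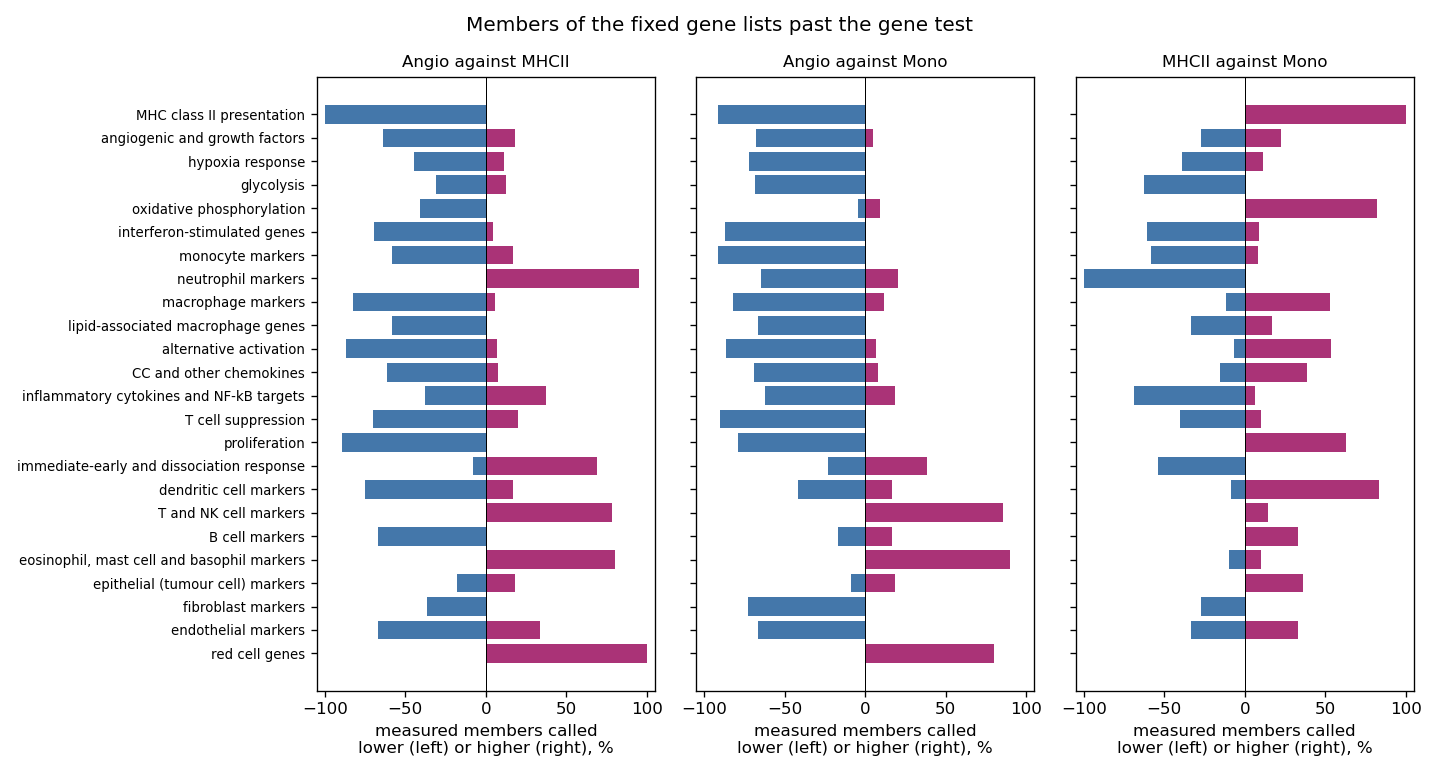
Percent of the measured members of each of the 24 tested gene lists called higher (bars to the right) or lower (bars to the left) in the population named first, in the 3 comparisons, by edgeR at an adjusted p under 0.05. Granulocyte and T and NK cell lists extend to the right and MHC class II, macrophage and proliferation lists to the left in Angio against MHCII.

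The comparison of Angio with Mono set the same Angio libraries beside the Ly6C/G-positive cells. The gates themselves select for lower monocyte, neutrophil and MHC class II genes in Angio, so those lists in part restate the sort. Eosinophil and basophil genes and Retnla were again far higher in Angio, while interferon, monocyte and macrophage genes were lower. Retnla stood at 6097 ± 2038 CPM in Angio and 47.8 ± 12.9 CPM in Mono (log2 fold change 7.0, SE 0.54, edgeR adjusted p = 2.64e-07), with all 4 Angio libraries above all 4 Mono libraries. The antiviral gene Ifit1 stood at 18.5 ± 10.3 CPM in Angio and 579 ± 29.1 CPM in Mono (log2 fold change -4.96, SE 0.43, edgeR adjusted p = 7.80e-07). Of the 13394 genes, 2763 were higher and 3048 lower in Angio, together 43.4%, and 2122 and 2481 of them differed by at least 2-fold.

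Of 10 eosinophil, mast cell and basophil markers 9 were higher in Angio than in Mono and 0 lower (camera adjusted p = 3.42e-07, and adjusted p = 0.00875 with an estimated correlation). Prg2 stood at 643 ± 189.6 against 3.71 ± 1.23 CPM, Mcpt8, a basophil protease, at 334 ± 86.2 against 5.68 ± 2.40 CPM, and Ccr3 at 1360.4 ± 250.5 against 24.9 ± 2.6 CPM. Prss34, a protease of basophils and mast cells, and Gata1, a transcription factor of the erythroid, mast cell and eosinophil lineages, were among the largest rises, at 58.0 ± 5.29 against 0.507 ± 0.510 CPM and 25.5 ± 6.46 against 0.242 ± 0.124 CPM. The Mono mean of Prss34 was 0.274 CPM without Mono 2. Tmem229a and Serpina11 stood at 18.9 ± 6.18 against 0.181 ± 0.13 CPM and 27.1 ± 4.59 against 0.181 ± 0.13 CPM. Of 14 T and NK cell markers 12 were higher and 0 lower (camera adjusted p = 3.60e-06, and adjusted p = 0.0139 with an estimated correlation), Gzma at 87.0 ± 23.2 against 3.71 ± 0.635 CPM and Nkg7 at 65.8 ± 19.4 against 6.54 ± 0.527 CPM. Of 5 red cell genes 4 were higher (camera adjusted p = 0.0210, but adjusted p = 0.210 with an estimated correlation). Neutrophil markers split, with 13 of 20 lower and 4 higher in Angio (camera adjusted p = 0.00253, but adjusted p = 0.210 with an estimated correlation). The receptors Csf3r and Cxcr2 stood at 38.9 ± 7.85 against 638 ± 5.81 CPM and 58.9 ± 7.85 against 685 ± 73.9 CPM. The 4 that were higher, named after their values were seen, were Retnlg (7165 ± 2479.9 against 1058 ± 264 CPM), G0s2 (12094 ± 4222 against 5231 ± 1234 CPM), Camp (754 ± 262 against 292 ± 79.3 CPM) and Elane (10.5 ± 1.47 against 5.98 ± 1.25 CPM). The call of G0s2 ended without Angio 1, Mono 2, Mono 3 or Mono 4 (edgeR adjusted p = 0.0623, 0.0607, 0.0596 and 0.0543). The call of Elane ended without Angio 1, Angio 3, Angio 4, Mono 2, Mono 3 or Mono 4 (edgeR adjusted p = 0.0609 to 0.134).

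Of 23 interferon-stimulated genes 20 were lower in Angio than in Mono and 0 higher (median -2.62; camera adjusted p = 2.55e-11, and adjusted p = 0.00207 with an estimated correlation), Rsad2 at 20.7 ± 5.55 against 396 ± 28.9 CPM. Monocyte markers were lower in 11 of 12 members and higher in 0 (camera adjusted p = 8.37e-07, and adjusted p = 0.00316 with an estimated correlation), with the chemokine receptor gene Ccr2 at 51.4 ± 9.48 against 577 ± 71.0 CPM. Macrophage markers were lower in 14 of 17 and higher in 2 (camera adjusted p = 1.52e-07, and adjusted p = 0.00207 with an estimated correlation). Alternative activation genes were lower in 13 of 15 and higher in 1 (camera adjusted p = 8.20e-07, and adjusted p = 0.00875 with an estimated correlation), and lipid-associated macrophage genes in 8 of 12 and higher in 0 (camera adjusted p = 8.75e-04, and adjusted p = 0.0157 with an estimated correlation). Mrc1 stood at 11.1 ± 2.29 against 198 ± 8.66 CPM, the folate receptor gene Folr2 at 0.373 ± 0.535 against 16.2 ± 3.23 CPM and the lipid droplet gene Plin2 at 331 ± 14.7 against 2307 ± 89.5 CPM. Angiogenic and growth factors were lower in 15 of 22 and higher in 1 (camera adjusted p = 9.53e-06, and adjusted p = 0.00712 with an estimated correlation), Adm, which encodes the vasodilator adrenomedullin, at 1.28 ± 0.871 against 17.8 ± 3.07 CPM. Without Angio 2 the Angio means were 0.109 CPM for Folr2 and 0.852 CPM for Adm. Hypoxia response genes were lower in 13 of 18 and higher in 0 (camera adjusted p = 4.54e-05, and adjusted p = 0.00712 with an estimated correlation). Ndrg1 stood at 26.7 ± 5.92 against 298 ± 46.9 CPM and the glycolytic regulator gene Pfkfb3 at 50.6 ± 16.0 against 373 ± 90.8 CPM. Glycolysis genes were lower in 11 of 16 and higher in 0 (camera adjusted p = 2.67e-04, but adjusted p = 0.0585 with an estimated correlation), the glucose transporter gene Slc2a1 at 29.1 ± 2.88 against 99.2 ± 8.13 CPM. T cell suppression genes were lower in 9 of 10 and higher in 0 (camera adjusted p = 6.30e-05, and adjusted p = 0.00712 with an estimated correlation). Cd274, which encodes PD-L1, stood at 87.3 ± 35.8 against 1156 ± 103 CPM, Nos2 at 5.33 ± 1.28 against 95.9 ± 7.79 CPM and Arg1 at 70.9 ± 15.7 against 949 ± 72.3 CPM.

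MHC class II presentation genes were lower in 11 of 12 members and higher in 0 (camera adjusted p = 2.49e-07, and adjusted p = 0.0438 with an estimated correlation), Cd74 at 251 ± 12.1 against 2615 ± 196 CPM. Inflammatory cytokines and NF-kB targets were lower in 10 of 16 and higher in 3 (camera adjusted p = 0.00400, and adjusted p = 0.0209 with an estimated correlation), the inflammasome sensor gene Nlrp3 at 66.8 ± 8.65 against 832 ± 39.7 CPM. Proliferation genes were lower in 15 of 19 and higher in 0 (camera adjusted p = 6.30e-05, and adjusted p = 0.0168 with an estimated correlation). Fibroblast markers were lower in 8 of 11 and higher in 0 (camera adjusted p = 0.0186, and adjusted p = 0.0493 with an estimated correlation). Chemokines were lower in 9 of 13 and higher in 1 (camera adjusted p = 8.42e-04, but adjusted p = 0.341 with an estimated correlation), Ccl2 at 43.6 ± 12 against 658 ± 119 CPM. The platelet chemokine gene Ppbp stood at 0.388 ± 0.192 against 16.0 ± 2.03 CPM and Cd83 at 7.49 ± 6.25 against 294 ± 53.8 CPM (4.42 CPM in Angio without Angio 2). Col14a1 stood at 0.487 ± 0.190 against 20.1 ± 2.89 CPM, Mrgpra2a at 4.41 ± 2.06 against 167 ± 18 CPM and the myelin gene Pmp22 at 0.443 ± 0.338 against 16.6 ± 2.95 CPM. The lists that did not pass camera were oxidative phosphorylation (2 of 22 higher, 1 lower, adjusted p = 0.143), dendritic cell markers (2 of 12 higher, 5 lower, 0.355), B cell markers (1 of 6 higher, 1 lower, 0.373), epithelial markers (2 of 11 higher, 1 lower, 0.355) and endothelial markers (0 of 3 higher, 2 lower, 0.228). Among dendritic cell markers the transcription factor gene Batf3 was higher, at 36.2 ± 13.6 against 3.97 ± 1.26 CPM. Immediate-early genes had 5 of 13 higher and 3 lower (adjusted p = 0.778), with a median log2 fold change of 0.23 and a mean of -0.16. Adjusted over the list alone, the counts were 14 lower for hypoxia response, 0 higher and 0 lower for oxidative phosphorylation, 21 lower for interferon-stimulated genes and 10 lower for chemokines. They were 4 higher for inflammatory cytokines, 1 higher for T cell suppression, 13 higher for T and NK cell markers, 0 higher for B cell markers, and equal to those above for the remaining lists.

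On log2(TPM + 1) values limma called 1992 genes lower in Angio than in Mono in place of 3048. Without Mono 1, Angio 2 and MHCII 2, 12 of 22 oxidative phosphorylation genes were higher in Angio than in Mono and 2 lower, and the list passed camera (adjusted p = 0.0115). Chemokines then had 3 higher, angiogenic and growth factors 2 higher, hypoxia response, monocyte and T cell suppression lists 1 higher each, immediate-early genes 6 lower with 5 higher, and B cell markers 4 of 8 lower with 2 higher. With GC and length offsets oxidative phosphorylation had 6 higher and 0 lower, inflammatory cytokines 5 higher, immediate-early genes 5 higher and 5 lower, B cell markers 0 higher and endothelial markers 1 lower.

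**Figure D3:**
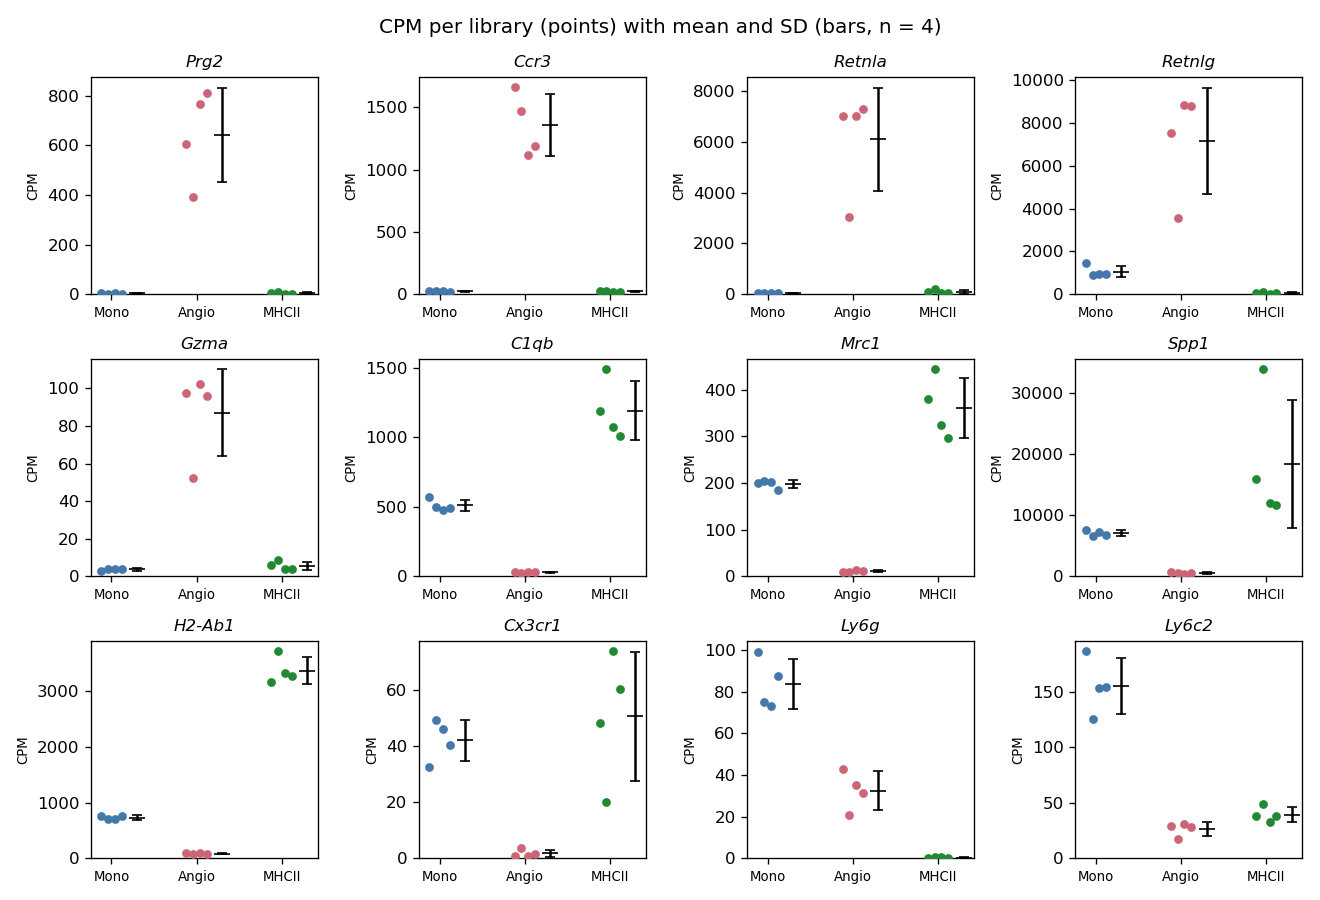
CPM of 12 genes in each library (points, y axis in CPM from 0) by population (x axis), with the mean and SD of the 4 libraries of each population beside them. Prg2, Ccr3, Retnla, Retnlg and Gzma are highest in Angio, C1qb, Mrc1, Spp1 and H2-Ab1 in MHCII, and Ly6g and Ly6c2 in Mono, and Cx3cr1 is lowest in Angio.

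The comparison of MHCII with Mono set the MHC-II-positive cells beside the Ly6C/G-positive ones. The gates themselves select for lower monocyte and neutrophil genes and higher MHC class II genes in MHCII, so those lists in part restate the sort. Neutrophil genes were far lower in MHCII, and antigen presentation and dendritic cell genes were higher in it. Chil1, a chitinase-like protein of neutrophil granules and macrophages, stood at 1.01 ± 0.247 CPM in MHCII and 454 ± 33.9 CPM in Mono (log2 fold change -8.81, SE 0.26, edgeR adjusted p = 1.30e-10), with all 4 MHCII libraries below all 4 Mono libraries. Ccl17 stood at 110.0 ± 88.8 CPM in MHCII and 3.22 ± 0.499 CPM in Mono (log2 fold change 5.09, SE 0.50, edgeR adjusted p = 5.69e-06), with no overlap of the libraries. Its MHCII mean was 66.4 CPM without MHCII 2. Of the 13394 genes, 2877 were higher and 2551 lower in MHCII, together 40.5%, and 1934 and 2029 of them differed by at least 2-fold, with 1011 in place of 1934 without MHCII 2.

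All 20 measured neutrophil markers were lower in MHCII than in Mono (median -6.31; camera adjusted p = 1.04e-23, and adjusted p = 0.0113 with an estimated correlation). Stfa2 stood at 1.63 ± 0.766 against 348 ± 137 CPM and the chemoattractant gene Prok2 at 1.37 ± 0.899 against 559 ± 112 CPM. Il1f9, an interleukin 1 family cytokine, stood at 0.773 ± 0.615 against 271 ± 49.2 CPM, Mrgpra2b at 1.26 ± 0.843 against 758 ± 91.5 CPM and Asprv1 at 0.419 ± 0.144 against 228 ± 7.76 CPM. The MHCII mean of Il1f9 was 0.466 CPM without MHCII 2. Cxcr1, an interleukin 8 receptor gene, had 2 counts in MHCII and 769 in Mono, a ratio of 548 per unit of library size (95% exact binomial interval 151 to 4530). Monocyte markers were lower in 7 of 12 members and higher in 1 (camera adjusted p = 0.00142, and adjusted p = 0.0319 with an estimated correlation). Inflammatory cytokines and NF-kB targets were lower in 11 of 16 and higher in 1 (camera adjusted p = 4.18e-05, and adjusted p = 0.0113 with an estimated correlation), Clec4e at 98.5 ± 9.46 against 736 ± 51.1 CPM. The member that was higher was Il12b, at 22.9 ± 12.4 against 2.61 ± 1.16 CPM. Interferon-stimulated genes were lower in 14 of 23 and higher in 2 (camera adjusted p = 6.54e-04, and adjusted p = 0.0356 with an estimated correlation). Hypoxia response genes were lower in 7 of 18 and higher in 2 (camera adjusted p = 0.00291, and adjusted p = 0.0338 with an estimated correlation), the prolyl hydroxylase gene Egln3 at 33.0 ± 2.97 against 212 ± 16.3 CPM. Glycolysis genes were lower in 10 of 16 and higher in 0 (camera adjusted p = 0.00185, but adjusted p = 0.116 with an estimated correlation), the lactate transporter gene Slc16a3 at 16.5 ± 12.4 against 219 ± 96.5 CPM. Immediate-early genes were lower in 7 of 13 and higher in 0 (camera adjusted p = 2.17e-04, but adjusted p = 0.119 with an estimated correlation), Egr1 at 194 ± 83.9 against 1074 ± 99.7 CPM.

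All 12 MHC class II presentation genes were higher in MHCII than in Mono (camera adjusted p = 2.38e-09, and adjusted p = 0.0367 with an estimated correlation), H2-Oa at 26.4 ± 9.90 against 1.62 ± 0.828 CPM. Dendritic cell markers were higher in 10 of 12 members and lower in 1 (median 2.0; camera adjusted p = 1.99e-04, and adjusted p = 0.0155 with an estimated correlation). Cd209a stood at 338 ± 178 against 18 ± 2.37 CPM and Xcr1, a chemokine receptor of cross-presenting dendritic cells, at 15.1 ± 1.29 against 2.97 ± 0.419 CPM. Plet1, Cd209d and Ccr6 were among the largest rises, at 87.6 ± 30.5 against 3.81 ± 1.57 CPM, 24.8 ± 19.2 against 2.29 ± 0.747 CPM and 17.3 ± 1.88 against 1.75 ± 0.359 CPM. Proliferation genes were higher in 12 of 19 and lower in 0 (camera adjusted p = 2.06e-04, and adjusted p = 0.0356 with an estimated correlation), the cyclin gene Ccnb2 at 71.9 ± 14.3 against 23.4 ± 5.32 CPM. Oxidative phosphorylation genes were higher in 18 of 22 and lower in 0 (camera adjusted p = 4.11e-05, but adjusted p = 0.178 with an estimated correlation), the complex I gene Ndufb8 at 692 ± 619.5 against 175 ± 42.6 CPM. Without MHCII 2 the MHCII means were 388 CPM for Ndufb8 and 15.4 CPM for Cd209d. Macrophage markers were higher in 9 of 17 and lower in 2 (camera adjusted p = 0.0196, but adjusted p = 0.0598 with an estimated correlation), C1qc at 2299 ± 798 against 769 ± 143 CPM. Alternative activation genes were higher in 8 of 15 and lower in 1 (camera adjusted p = 0.00411, but adjusted p = 0.0971 with an estimated correlation), the lectin gene Mgl2 at 107 ± 9.24 against 16.8 ± 3.37 CPM.

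The remaining lists did not pass camera in MHCII against Mono. Angiogenic and growth factors had 5 of 22 higher and 6 lower (adjusted p = 0.391), with Ptgs2, the inducible cyclooxygenase gene, at 102 ± 29.9 against 508 ± 22.9 CPM and Cxcl2 at 738 ± 259.6 against 3141 ± 396 CPM. T cell suppression genes had 1 of 10 higher and 4 lower (0.0676), with Cd274 at 188 ± 64.4 against 1156 ± 103 CPM. Chemokines had 5 of 13 higher and 2 lower (0.201), T and NK cell markers 2 of 14 higher and 0 lower (0.258), and B cell markers 2 of 6 higher and 0 lower (0.0750). Epithelial markers had 4 of 11 higher and 0 lower (0.0661), with Epcam, an adhesion gene of epithelia and some dendritic cells, at 60.3 ± 26.4 against 10.6 ± 2.21 CPM. Endothelial markers had 1 of 3 higher and 1 lower (0.801) and red cell genes 0 of 5 in either direction (0.891). In 3 lists the median and mean log2 fold changes differed in sign. Lipid-associated macrophage genes had a median of 0.23 and a mean of -0.09, with 2 of 12 higher and 4 lower (0.672). Fibroblast markers had a median of 0.22 and a mean of -0.24, with 0 of 11 higher and 3 lower (0.733). Eosinophil, mast cell and basophil markers had a median of 0.02 and a mean of -9.51e-05, with 1 of 10 higher and 1 lower (0.934), and a median of -0.02 with Epx at its bound. Adjusted over the list alone, the counts were 9 lower for hypoxia response, 19 higher for oxidative phosphorylation, 3 higher and 15 lower for interferon-stimulated genes and 4 higher for lipid-associated macrophage genes. They were 9 higher and 2 lower for alternative activation, 7 higher for chemokines, 0 higher for eosinophil, mast cell and basophil markers, 2 lower for fibroblast markers, and equal to those above for the remaining lists.

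On log2(TPM + 1) values limma called 1451 genes lower in MHCII than in Mono in place of 2551. Of the 13 lists called, 8 held with an estimated correlation. Without Mono 1, Angio 2 and MHCII 2 hypoxia response genes had 11 of 18 lower in MHCII than in Mono, alternative activation 2 lower, T and NK cell markers 1 higher and 1 lower, and B cell markers 4 of 8 higher. With GC and length offsets B cell markers had 4 of 6 higher, T and NK cell markers 4 higher and 1 lower, monocyte markers 2 higher, glycolysis and fibroblast lists 1 higher each, and endothelial markers 0 lower. Epithelial markers passed camera without MHCII 2 (adjusted p = 0.0322), T cell suppression likewise (0.031), and B cell markers without Mono 2 or Mono 3 (0.02 and 0.0234).

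Over the 3 populations, 1956 genes were highest in Angio, 1761 in MHCII and 1048 in Mono, each by passing both tests that involve the population. Genes lowest in a population, counted for Angio and MHCII after the data were seen, numbered 1963 in Angio, 1527 in MHCII and 624 in Mono. With limma on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter they numbered 1211, 1274 and 904 in Angio and 743, 825 and 473 in MHCII. Prg2, Ccr3, Retnla and Gzma were highest in Angio, H2-Ab1, C1qb, Mrc1 and Cd209a in MHCII, and Ly6c2, Csf3r, Cxcr2 and Cd274 in Mono. In both Ly6C/G-negative populations 624 genes were higher than in Mono and 1048 lower. Independent lists of these sizes would share 593.5 and 580.5 genes. The 624 shared higher genes lay near the first number and the 1048 shared lower genes above the second. Unchanged groups simulated against the same Mono libraries shared 0 in each direction over 20 simulations. No gene was changed in them, so hardly any could be called in either comparison. That 0 therefore does not measure what the common Mono libraries add to the overlap of the real calls. With the Mono libraries split between the comparisons, the shared higher genes numbered 98 to 131 and the shared lower genes 666 to 693. Each test then had fewer Mono libraries, so the fall cannot be put down to the shared libraries alone. Without Mono 2, Mono 3 or Mono 4 the shared higher genes numbered 329, 337 and 331, with the replicate number as a block 362, without Mono 1, Angio 2 and MHCII 2 together 1104, and with limma on log2(TPM + 1) and log2(TPM + 0.1) 1189 and 1213. With limma on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter, 631, 538 and 509 genes were highest in Mono, that is, lower in both other populations, in place of 1048.

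Genes named here with their positions in the GENCODE M21 annotation of GRCm38 are protein-coding, and the spans cover exons and introns. Prg2 lies on chromosome 2 from 84980461 to 84983632, Ccr3 on chromosome 9 from 124021972 to 124031689 and Retnla on chromosome 16 from 48842551 to 48844461. Spp1 lies on chromosome 5 from 104435118 to 104441050, Cyp26a1 on chromosome 19 from 37697798 to 37701536 and Ccl17 on chromosome 8 from 94810453 to 94812036, these and the genes before them on the plus strand. Chil1 lies on chromosome 1 from 134182176 to 134190181 on the plus strand and Cd209d on chromosome 8 from 3871824 to 3878555 on the minus strand. Levels of close paralogs, which the counting could have split between copies, are uncertain. They include Ly6c1 and Ly6c2, the Stfa genes, the Cd209 genes, Hba-a1 and Hba-a2, the Mrgpra2 genes and Lilrb4a. Intervals on ratios of counts cover counting error only, since amplified reads without molecular identifiers are not independent molecules.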

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

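The tests of depth, and of GC content and length within groups, in this part were chosen only after the result was seen. Values of 4 libraries were compared within each population for the named genes and for the measures of library quality, and a value was singled out where its gap to the nearest other library exceeded Dixon's 95% critical share of the range. This marked 48 of 401 groups of values, 12%, where chance marks about 5%, and genes of a single library are not independent of each other.

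In Mono 1 these levels lay above the other 3 libraries: H2-Eb1 at 1080 CPM (others 760 to 806), Ndufa4 at 226 (130 to 144), Cxcr2 at 795 (641 to 661), C1qc at 981 (682 to 728), Ccl7 at 567 (340 to 376), Atf3 at 644 (495 to 503), Hba-a1 at 164 (109 to 111), Plet1 at 6.15 (2.88 to 3.29), Cxcl2 at 3730 (2880 to 3020), Ero1l at 1710 (1470 to 1500), Ccl12 at 630 (316 to 355) and Hbb-bs at 1280 (752 to 788). Gzma, at 2.76 CPM, lay below 3.95 to 4.11, and the share of counts in CT010467.1, at 1.36%, below 1.86% to 1.94%. In Mono 4 the metalloproteinase gene Mmp8 lay below the others, at 380 CPM against 432 to 436.

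In Angio 2 the levels below the other libraries were H2-Eb1 at 82.1 CPM (others 148 to 157), H2-DMb1 at 7.48 (10.7 to 11.2), Ifi44 at 40.9 (73.6 to 77.8), Retnla at 3040 (7030 to 7290), Atf3 at 52.6 (66.1 to 68.1), Gzma at 52.4 (95.9 to 102), Il2rb at 56.3 (90.9 to 96.7) and Ndufa4 at 192 (391 to 400). Above them were Slc16a3 at 296 CPM (60.2 to 82.4), Arg1 at 94.3 (60.7 to 65.6), Igkc at 57.8 (3.27 to 8.01), Pecam1 at 88.8 (65.2 to 66.5), Adm at 2.58 (0.676 to 0.956) and the TMM factor at 1.18 (1.0 to 1.03). In Angio 1 the levels of Spp1, at 732 CPM, and Tyms, at 13.8 CPM, lay above 460 to 494 and 6.05 to 6.48 CPM. In Angio 3 Mrc1, at 14.5 CPM, lay above 9.66 to 10.5, and Cd3e, at 12.9 CPM, below 18.6 to 18.9.

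In MHCII 2 chemokine genes lay far above the other libraries, with Ccl12 at 4450 CPM (others 556 to 1160), Ccl7 at 2780 (354 to 730), Ccl8 at 3040 (414 to 805) and Ccl3 at 414 (125 to 158). Also above the others were Camp at 8.57 (3.12 to 3.54), Prg2 at 9.95 (2.98 to 3.45), H2-Aa at 5040 (2840 to 3180), Ankrd37 at 320 (71.8 to 113), Retnla at 201 (53.3 to 78.2), Tyms at 129 (46.5 to 59.6), Asprv1 at 0.635 (0.345 to 0.347), Il1f9 at 1.69 (0.416 to 0.518), Ms4a7 at 839 (220 to 322) and Xcr1 at 17.0 (14.3 to 14.6). The gap of Xcr1 was small, and the levels of Asprv1 lay near the floor. Ifit1, at 49.5 CPM, lay below 101 to 109.

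Of these 48 values, 43 belonged to Mono 1, Angio 2 and MHCII 2. Lower sequencing depth as the common cause was excluded, since only 1 of these 3 libraries, Mono 1, had the lowest total of its group. GC content and transcript length cannot be told apart from other causes. Across 13145 genes, which are not independent replicates, the deviation from the group's other libraries had a Spearman rho with length of -0.204 in Mono 1, 0.146 in Angio 2 and -0.253 in MHCII 2, neither all under 0.1 nor all at least 0.3 in size. With GC content rho was -0.155, 0.108 and -0.217 in the same order. In libraries that did not stand apart rho ran from -0.107 to 0.254 with length and from -0.218 to 0.211 with GC content. Their deviations were taken from means that include the library that stood apart. A difference in the cells sorted may also have set these libraries apart, but the design gives no label within a population, and no biological explanation was tested.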

How the results depend on the processing

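The tests without Mono 1, Angio 2 and MHCII 2, without CT010467.1, mitochondrial and haemoglobin genes, with GC and length offsets, and of genes lowest in Angio and MHCII, were chosen only after the data were seen. Of values recomputed for named genes, 4916 kept their side of the threshold and direction, 181 lost and 4 gained significance. The losses fell on 32 gene results, mostly Uqcrc2 (15 settings), Ndufa4 (8), Pfkl (7) and Ndufs1 (7) in Angio against Mono. In MHCII against Mono they were Krt18 (14), Mcpt8 (7) and Ptprc (7), and in Angio against MHCII Ly6c1 (13), Ly6c2 (12), Ighm (10), Ndufb8 (8), Spint2 (7) and Pecam1 (7). For camera p-values 1220 kept, 39 lost and 19 gained it, and of the counts 441 were within 1.5 times and 52 moved, given here or in the report. An estimated correlation gave 18 of the 39 losses, those named in the report. The others lay in Angio against MHCII. B cell, monocyte and oxidative phosphorylation lists lost the call without Mono 1, Angio 2 and MHCII 2 (adjusted p = 0.0504, 0.121 and 0.357) and with GC and length offsets (0.0526, 0.0739 and 0.125). The offsets also ended those of T cell suppression and immediate-early genes (0.0568 and 0.0641), and DESeq2 size factors that of red cell genes (0.0531). Single libraries left out ended those of B cell, monocyte, oxidative phosphorylation and red cell lists. Of the 19 gains 9 came without a filter (1.40e-04 to 0.0224), by hypoxia, glycolysis and fibroblast lists in Angio against MHCII, dendritic markers in Angio against Mono, and chemokine, T cell suppression, T and NK, B cell and epithelial lists in MHCII against Mono. Without the 3 libraries oxidative phosphorylation gained in Angio against Mono (0.0115). The other gains lay in MHCII against Mono: T cell suppression (0.0403) and epithelial markers (0.0333) without the 3 libraries, epithelial markers with only the 2 groups (0.0379) and offsets (0.0309), B cell markers with the block (0.0456), and 4 without single libraries, named in the report. Where none is stated, the cause was not tested.

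With an estimated correlation 9 lists passed for Angio against MHCII in place of 18 and 8 for MHCII against Mono in place of 13. Without a low-count filter, which tested 37801 genes, 7425 were higher in Angio than in MHCII and 4750 lower, 61.0% higher against 49.1%. DESeq2's Wald test gave 6606 and 4027, 62.1% higher. With limma on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter, genes lower in Angio than in Mono numbered 1992, 1962 and 1617. Genes higher were 62.4%, 61.6% and 71.5% of the calls, against 47.5%. Genes lower in MHCII than in Mono numbered 1451, 1444 and 1065, with 68.1%, 67.1% and 68.7% of calls higher against 53.0%. Unfiltered TPM gave 64.5% higher in Angio against MHCII. Genes highest in Mono, which are also those lower in both Ly6C/G-negative populations, numbered 631, 538 and 509 on these scales, genes lowest in Angio 1211, 1274 and 904, and in MHCII 743, 825 and 473. Genes at least 2-fold higher in Angio than in MHCII numbered 7055 without a filter, 5904 with DESeq2, and 1932 and 1897 with limma on log2(TPM + 1) with and without a filter. On this scale, in the same order, genes at least 2-fold lower than in Mono numbered 1421 and 1260 in Angio and 1048 and 852 in MHCII, and 1293 in MHCII on log2(TPM + 0.1). Genes at least 2-fold higher in MHCII than in Mono numbered 1011 without MHCII 2 and 1267 without the 3 libraries.

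Genes higher in both Ly6C/G-negative populations than in Mono, 624, numbered 1189 and 1213 with log2(TPM + 1) and log2(TPM + 0.1) and 1104 without Mono 1, Angio 2 and MHCII 2. With the 4 Mono libraries split between the comparisons they numbered 122, 99, 124, 104, 131 and 98, and the genes lower in both, 1048, numbered 689, 673, 693, 681, 691 and 666, with fewer libraries per test.

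The replicate number as a block gave 3285 higher and 3273 lower in Angio against MHCII, 2405 and 2732 in Angio against Mono, and 2145 and 2208 in MHCII against Mono, and 362 genes higher in both Ly6C/G-negative populations. The labels tie no numbers to animals, and 5 of 12 pairs had a correlation of deviations over 0.1 (0.163 to 0.314), so numbers were not taken as pairs. As a hint from the data, 1 of 12 libraries correlated best within its number.

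Leaving out each library in turn gave 3388 to 4287 higher and 3345 to 3755 lower genes for Angio against MHCII, 2349 to 3005 and 2654 to 3164 for Angio against Mono, and 2062 to 3065 and 2109 to 2810 for MHCII against Mono. Lists called numbered 15 to 18, 18 to 18 and 13 to 15. Genes highest in Mono numbered 848 to 1270, in Angio 1713 to 2760 and in MHCII 1348 to 1977. Genes higher in both Ly6C/G-negative populations numbered 329 to 715, and genes lower in both 848 to 1270.

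Results that turned direction passed no test in the main setting or in the setting where they turned. The gains among named genes fell on such results, Ptprc in Angio against Mono in 3 other settings and Hbb-bs in MHCII against Mono in 1. In Angio against Mono Ptprc turned to log2 fold changes of -0.11 without a filter, -0.0098 without Mono 2 and -0.00093 without Angio 1, Itgam to -0.083 without the 3 libraries and Pecam1 to 0.017 with the offsets. In MHCII against Mono Sparc turned to -0.078 without MHCII 2 and -0.016 without the 3 libraries, and Hbb-bs to -0.044 without MHCII 2. As adjusted p-values, immediate-early genes in Angio against Mono had 0.352 without a filter, 0.809 without the 3 libraries and 0.874 with the offsets. Inflammatory genes in Angio against MHCII had 0.777 with at least 10 counts in 8 libraries, 0.922 with only the 2 groups, 0.991 without Angio 3 and 0.915 with the offsets. Eosinophil genes in MHCII against Mono had 0.952 and 0.886 in the first 2 of these settings, 0.716 without MHCII 2, 0.76 without the 3 libraries and 0.923 with the offsets, and red cell genes 0.716, 0.856 and 0.923 in the last 3. Other range ends over single libraries did not turn: Ptprc 0.14 without Mono 1, Sparc 0.43 and Hbb-bs 1.18 without MHCII 4, inflammatory genes 0.858 without MHCII 3, eosinophil genes 0.9704 without Mono 4, and red cell genes 0.669 without MHCII 4 and 0.919 without Mono 4.

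Of 244 named results, 7 had no value with at least 10 counts in 8 libraries, 7 without the CT010467.1, mitochondrial and haemoglobin genes and 1 with the offsets, since their genes were left out. With 2 counts of Cxcr1 in MHCII and 769 in Mono, counting error left a 95% interval from 151 to 4530 on their ratio.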

Other observations

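The tests of gate content, of carry-over, of GC and length offsets, of exchanged labels and of dilution in this part were chosen only after the data were seen, and the splits of the samples were set out before.

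Genes outside the fixed lists also rose in Angio, and those named next were chosen after their values were seen. Alox15, a lipoxygenase that is abundant in mouse eosinophils, stood at 1044 ± 159 CPM in Angio, 13.9 ± 2.89 CPM in Mono and 19.0 ± 4.41 CPM in MHCII (n = 4). Cebpe, a transcription factor of granulocyte maturation, stood at 194 ± 25.9 CPM in Angio against 9.06 ± 1.47 in Mono and 4.55 ± 1.68 in MHCII. The cytokine gene Il4 stood at 22.7 ± 3.09 CPM in Angio, 0.349 ± 0.126 in Mono and 0.256 ± 0.325 in MHCII, and Gata2, a transcription factor of basophils and mast cells, at 12.6 ± 5.17, 0.271 ± 0.131 and 0.350 ± 0.192 CPM. Il1rl1, the interleukin 33 receptor gene, stood at 87.3 ± 17.8, 1.48 ± 0.192 and 3.06 ± 2.90 CPM in the same order, and Cd200r3, a receptor gene of basophils and mast cells, at 59.7 ± 12.2, 3.66 ± 1.36 and 7.79 ± 2.87 CPM. Ear1 and Ear6, eosinophil-associated ribonucleases whose reads could be shared with their paralogs, stood at 75.6 ± 25.1 and 57.2 ± 13.1 CPM in Angio. Without MHCII 2 the MHCII means were 1.61 CPM for Il1rl1 and 0.0943 CPM for Il4. Each of these genes passed the edgeR test against both other populations. The most abundant members of the fixed eosinophil, mast cell and basophil list were Ccr3 at 1360.4 CPM, Prg2 at 643 CPM and Mcpt8 at 334 CPM in Angio. This list shared 0 genes with the other lists, while the neutrophil list shared 1, Ly6g, with the gate markers and the macrophage list 1, Mrc1, with another list.

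A hypothesis is that cells other than macrophages inside the Angio gate, which the labels give as CD11b+, Ly6C/G-negative, CX3CR1-negative and MHC-II-negative with no marker against eosinophils or basophils, gave much of its granulocyte signal. The tables cannot decide it, since the values it needs restate the pattern: 8 of 10 measured eosinophil, mast cell and basophil markers were higher in Angio than in both other populations, the whole list summing to 2630 ± 263 CPM against 55.6 ± 4.22 in Mono and 52.3 ± 14.2 in MHCII, and macrophage markers had medians of -3.87 against MHCII and -3.38 against Mono. Carry-over of cells in the mix measured in Mono could not by itself give the eosinophil and basophil genes, since 9 members were higher in Angio than in Mono. Those values are part of the pattern, and carry-over of a subset of Ly6C/G+ cells was not tested. With GC and length offsets, fitted over all genes, the median of these markers against MHCII was 5.165, and 5.11 without. A trend with GC content and transcript length common to all genes was therefore excluded as its source. Carry-over of Ly6C/G+ cells as the source of the neutrophil genes cannot be told apart from other sources, since 4 of 20 markers were higher in Angio than in Mono while the list summed to 37320 ± 11400 CPM in Angio and 65870 ± 22500 CPM in Mono. A granulocyte gene programme in macrophages themselves stays open and was not tested.

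A further pattern was that most angiogenic and growth factors were lower in Angio than in MHCII, although the population is called pro-angiogenic. Exchanged Angio and MHCII labels were excluded, since 4 gate genes (Cx3cr1, H2-Aa, H2-Ab1 and H2-Eb1) were lower in every library labelled Angio than in every library labelled MHCII. Dilution of macrophage RNA by other cells in Angio cannot be told apart from a lower expression in macrophages. The 22 members had a median log2 fold change of -1.74 and the 17 macrophage markers of -3.87, a difference of 2.13 whose 95% bootstrap interval over genes, -0.096 to 3.914, decided neither way. A difference between the sorted populations stays open as well.

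Splits of the samples were counted for each model result, the real split among them. For Angio against MHCII 1 of the 35 splits of the 8 libraries gave as many changed genes. The real split gave 7288 and the highest other 1075. The real split thus gave the most calls. The libraries were sorted to differ, so this outcome was largely set by the sort, and it says nothing about further animals. For the lists called, 1 of 35 splits gave as many, with 18 and 17. For Angio against Mono 1 of 35 splits gave as many changed genes, with 5811 and 2. For MHCII against Mono it was 1 of 35, with 5428 and 0. The other splits mix the sorted populations, which widens the spread within their groups and leaves few genes to call. The lead of the real splits therefore does not decide how many of the calls are due to chance. For the number of lists called against Mono the real split did not lead alone. For Angio 3 of 35 splits gave as many, with 18 in the real split and 18 in the highest other, and for MHCII 3 of 35, with 13 and 13. The tied splits kept 3 of the 4 libraries of each population together. They carried part of the real contrast, so these counts do not decide whether a random labelling could give as many lists. For genes highest in a population 1 of 100 regroupings of the 12 libraries gave as many, with 4765 and 1565. For genes shared by both Ly6C/G-negative populations against Mono 2 of 100 gave as many, with 1672 in the real grouping and 3413 in another, which set the 4 Angio libraries against mixtures of the others and so followed the structure of the samples. The other 98 shared 0 genes, and in 96 of these 98 no population was kept whole, so the regroupings do not decide whether the comparisons share genes beyond chance.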
